A study of Mus musculus with 9 samples.

How the data were processed

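RNA was measured on 9 Affymetrix mouse arrays, with 3 arrays in each of 3 groups. The cells were Ainv15 mouse embryonic stem (ES) cells carrying a doxycycline-inducible Cdx2 construct with a V5 tag. The first group was ES cells at day 0, which had been grown on a layer of mitomycin-C-treated fibroblasts. The second was day 5 motor neuron cultures, made from embryoid bodies that received 1 µM all-trans retinoic acid and 0.5 µM hedgehog agonist from day 2. The third also received these signals from day 2, plus doxycycline at 2 µg/ml on day 3 for 6 to 8 hours and basic FGF at 100 ng/ml. These cultures are called Cdx2 and FGF cultures here. The growth protocol also describes a wash after doxycycline and lower concentrations of retinoic acid and hedgehog agonist given with FGF, and does not say which cultures this applied to. Doxycycline, Cdx2 and FGF were given together, so their parts cannot be separated.

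Per the labels' protocols, RNA was amplified and labelled with a NuGEN Ovation kit. GCRMA and limma are named in the submitters' processing notes, without versions or options. The values deposited by the authors were log2 expression levels per probe set, background-corrected and normalized between arrays. They ran from a floor of 2.165, shared by the 9 arrays, to 16.12, and were not centred per gene. The log2 scale was read from the values, since no unit line was at hand. The values were used without further normalization. For arrays, their number limits the precision.

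The table held 45101 probe sets. Of these, 34958 named 1 gene symbol, 932 named several and 9211 had no name here; 64 of the probe sets were Affymetrix controls. The Entrez identifiers of 34754 probe sets were found in the GRCm38.p6 gene table, which was used for names only, and 0 symbols had to be updated. No coordinates are given. A gene was represented by the probe set with the highest mean over the 9 arrays, out of 18193 genes, of which 9010 had more than 1 probe set. Genes over 4 on the log2 scale on at least 3 of the 9 arrays were tested, which left 10911.

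Group means were fitted to all 9 arrays with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in R 4.3.3, leaving 6 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the genes tested. A gene was called higher or lower at an adjusted p under 0.05 and an absolute log2 difference of at least 1. Standard errors (SE) come from this fit, and standard deviations (SD) from the 3 arrays of a group. Where all 3 arrays of the dimmer group lay under 4, the fold is given as a lower bound, with values under 4 raised to 4. Folds of named genes with only some arrays of the dimmer group under 4 are given in the same way, which was chosen after their values were seen; 2 of the 3 arrays lay under 4 for Sncg, Tagln3, Acta2, Tagln, Krt19, Egr1 and Snai2, and 1 for Slc18a3. The labels state no separate origin for the cultures behind the 3 arrays of a group, so p-values measure only the spread between arrays, which may be technical.

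A total of 25 gene lists, with 503 entries of which 469 had a probe set of their own, the tests, the thresholds and the rule for named genes were fixed before the data were examined. The lists covered pluripotency, motor neurons and ventral progenitors, pan-neuronal genes, neural progenitors, Hox paralogs 1 to 5, 6 to 9 and 10 to 13, retinoid, hedgehog and FGF and ERK responses, tail bud and caudal progenitors, midbrain and hindbrain, motor columns, ventral interneurons and floor plate, glia, neural crest, endoderm, mesoderm, trophoblast, intestinal epithelium, fibroblasts, Polycomb and H3K27 demethylase genes, cell cycle, stress and apoptosis, and hypoxia and glycolysis. Several genes belong to more than 1 list. Each list's shift was tested with limma's camera at a preset correlation of 0.01 and adjusted over the lists of a comparison. The same test with an estimated correlation, and fry, were run beside it. Camera compares a list with the other genes tested, while fry tests whether its members move one way on balance. Calls were also adjusted over the list alone. The list of Hox paralogs 10 to 13 had 2 tested members and was not tested as a set.

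Named genes were Cdx2; the 6 genes with the largest rise and the 6 with the largest fall (3 and 3 against ES cells for the Cdx2 and FGF cultures) among called genes whose groups did not overlap, ranked after values under 4 were raised to 4; up to 4 members of each list by the same rank, called members first; every Hox gene; and, for the effect of Cdx2 and FGF, every Polycomb list member. Predicted or clone names were counted in the ranks but not named. Array quality was compared through control probe sets with exact two-sided permutation tests.

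The alternatives tried were quantile normalization again, median centring, no filter and a filter at 6, values under 4 raised to 4, other variance priors, the mean of a gene's probe sets, no probe sets of the x_at or s_at kinds, each probe set by itself, only the 6 arrays compared, array weights, a replicate block, no minimum fold change, other list tests, and each array left out in turn. ES arrays 2 and 3 were left out together, and genes whose probe sets differed were left out, as alternatives chosen after seeing the data. The calling steps were tested on simulated data with 10911 genes per comparison, with 100 genes changed at each size. Simulated values were normal, with no floor and 1 SD per gene pooled over the groups, and the changed genes had middle mean levels. The rates therefore do not describe genes near the floor or the wider spread of the ES arrays. Recovery at log2 changes of 1.5 and 3 was 79% and 94% for day 5 motor neuron cultures against ES cells, with 7 false calls. It was 74% and 98% for Cdx2 and FGF cultures against motor neuron cultures, with 5 false calls, and 73% and 97% for Cdx2 and FGF cultures against ES cells, with 4 false calls. A simulated shift of the cell cycle list was recovered in each comparison, with 0 other lists called. Probe sets without exactly 1 gene name were left out of the gene counts.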

Results

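Gene expression was measured in mouse ES cells, in day 5 motor neuron cultures made from such cells with retinoic acid and a hedgehog agonist, and in day 5 cultures in which Cdx2 was also induced and FGF added. Each group had 3 arrays, and differences are on the log2 scale, the first-named group minus the second. The series concerns how Cdx2, a caudal homeobox factor, and signalling factors set the rostrocaudal Hox identity of motor neuron progenitors and their chromatin. Only the expression arrays were analysed here. A mean of 44.6% of probe sets exceeded 4 on the ES arrays, 43.6% on the motor neuron arrays and 43.7% on the Cdx2 and FGF arrays. Correlations between arrays of a group were 0.945 to 0.953 in ES cells, 0.987 to 0.993 in motor neuron cultures and 0.995 in Cdx2 and FGF cultures. The median within-group SD was 0.377, 0.149 and 0.114. The first principal component held 75.9% of the variance and the second 17%.

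The ES arrays stood apart in control probe sets that report on RNA amplification. The 3′ probe set for 18S ribosomal RNA read 5.86, 6.6 and 6.59 on the ES arrays, 15.49, 15.51 and 15.45 on the motor neuron arrays, and 15.42, 15.39 and 15.32 on the Cdx2 and FGF arrays. The 3′ minus 5′ difference of the Actb controls averaged 2.07 ± 0.217 (SD, n = 3) in ES cells and -0.04 ± 0.01 in motor neuron cultures. That of the transferrin receptor controls (Tfrc) was 6.25 ± 0.637 against -1.5 ± 0.0945. The exact two-sided permutation p was 0.1 for Actb and for Tfrc, the smallest that 3 arrays against 3 can give, and 0.2 for Gapdh. Replication-dependent histone genes, whose mRNAs lack a poly(A) tail, had a median difference of 3.06 between motor neuron cultures and ES cells over 7 tested genes, with 5 higher and 1 lower. Their median level per array overlapped, at 8.58, 7.16 and 6.56 on the ES arrays and 8.41, 8.13 and 9.16 on the motor neuron arrays. Between the 2 kinds of day 5 culture the median difference was -0.04, with 1 gene higher. Between Cdx2 and FGF cultures and ES cells it was 3.08, so that every comparison with ES cells stands beside this difference between arrays.

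**Figure D1:**
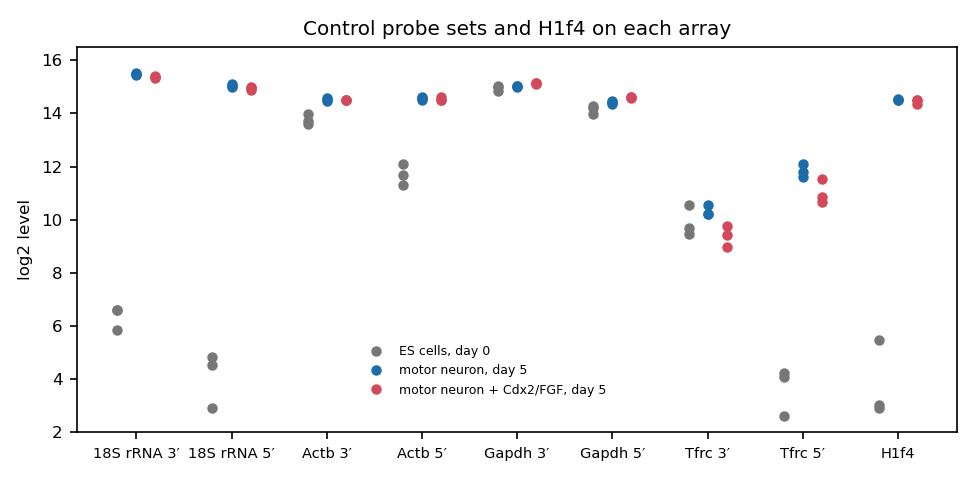
Levels of control probe sets and of the histone gene H1f4 on each of the 9 arrays; the vertical axis is the log2 level, each point is 1 array, and colours mark the 3 groups. The ES arrays read 5.86 to 6.6 for the 18S 3′ probe set, and the day 5 arrays 15.32 to 15.51.

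Cdx2 itself was at the floor without induction and was raised in the cultures that had received doxycycline. The Cdx2 probe set with the higher mean read 2.17 on each ES array, 2.17, 2.17 and 2.24 in motor neuron cultures, and 8.27, 8.99 and 8.59 in Cdx2 and FGF cultures. The rise over motor neuron cultures was at least 24.5-fold (log2 difference 6.42, SE 0.23, adjusted p = 1.15e-07). A second probe set averaged 3.3, 2.63 and 6.7 in the same order. The arrays do not separate transcripts of the construct from those of the endogenous gene.

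The first comparison asked what differentiation to day 5 with retinoic acid and hedgehog agonist changed. Pluripotency genes were lower, and neuronal and Hox genes higher, in motor neuron cultures. Of the tested genes, 30 of 31 pluripotency genes were lower and 28 of 32 pan-neuronal genes higher. In the list of Hox paralogs 1 to 5, 11 of 11 tested genes were higher, none of them of paralog 1. With an estimated correlation between genes the pluripotency call held (adjusted p = 0.0243), while those of the pan-neuronal and Hox lists were lost (adjusted p = 0.0847 for both). Hoxb5 rose at least 1130-fold, from 2.58 ± 0.04 to 14.14 ± 0.06 (SD, n = 3; log2 difference 11.56, SE 0.16, adjusted p = 2.59e-10). Nanog, a core pluripotency factor, was at least 700-fold lower, going from 13.45 ± 0.33 to 2.17 (log2 difference -11.29, SE 0.23, adjusted p = 1.21e-09). Of 10911 genes tested, 2826 (25.9%) were higher and 3346 (30.7%) lower in motor neuron cultures, with all 3 arrays of the dimmer group under 4 for 454 and 719 of them.

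The largest rises beside Hoxb5 were those of the linker histone gene H1f4, the orphan nuclear receptor gene Nr2f1 (at least 811-fold), the synuclein gene Sncg (at least 792-fold), the antisense transcript Hoxb5os (at least 754-fold) and the neuronal gene Tagln3 (at least 582-fold). H1f4 went from 3.81 ± 1.44 to 14.52 ± 0.02, and belongs to the histone genes that moved with the amplification controls. The largest falls were in Dppa2 (at least 1040-fold lower), the ES cell growth factor gene Fgf4 (at least 1030-fold lower), AU018091, the Nodal co-receptor gene Tdgf1 (at least 828-fold lower), Ooep and Nanog. The pluripotency list had a median of -8.72, or -7.18 with values under 4 raised to 4 (camera adjusted p = 4.63e-14; 0.0243 with an estimated correlation).

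Neural lists rose. In the motor neuron and ventral progenitor list, 16 of 18 genes were higher and 1 lower, with a median of 5.41, or 4.62 with low values raised (adjusted p = 2.07e-06; 0.0243 with an estimated correlation). Nkx6-1, a ventral progenitor factor, was at least 264-fold higher, the proneural gene Neurog2 at least 174-fold, the vesicular acetylcholine transporter gene Slc18a3 at least 138-fold, and the motor neuron factor gene Isl1 206-fold. The pan-neuronal median was 4.48, or 4.18 with low values raised (adjusted p = 8.76e-11); this call was lost at adjusted p = 0.0847 with an estimated correlation. Neurod4 was at least 506-fold higher and Dcx, a microtubule protein of migrating neurons, at least 456-fold. In the neural progenitor list 18 of 21 genes were higher and 1 lower, with a median of 4.3 that did not change with low values raised (adjusted p = 1.24e-06; 0.0243 with an estimated correlation). Its members included Fabp7, at least 483-fold higher, and Hes5, a Notch target, at least 219-fold higher.

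The Hox paralogs 1 to 5 had a median of 8.54, or 7.17 with low values raised (adjusted p = 1.04e-07), with adjusted p = 0.0847 with an estimated correlation. Hoxb1 and Hoxd1 were too dim to be tested, at 2.2 and 2.19 in ES cells and 2.17 and 4.04 in motor neuron cultures. Hoxa2, Hoxa3, Hoxa5, Hoxb2, Hoxb4, Hoxb5, Hoxc5 and Hoxd3 lay under 4 on all ES arrays. They therefore had little room to come out lower. Hoxb4, Hoxa3 and Hoxa5 were at least 480-fold, 389-fold and 386-fold higher, and Hoxb6 at least 506-fold. Hoxb6 and Hoxd8 were the 2 of 9 genes called higher among paralogs 6 to 9. Hoxd8 stood at 4.89 ± 0.75 against 3 ± 0.23 (log2 difference 1.89), but its second probe set went from 5.16 to 3.1 and the mean of both gave -0.08. The call also ended with low values raised (0.89) and with array weights (adjusted p = 0.0556). Hoxc8 and Hoxd9 were lower, from 7.37 ± 0.78 to 2.31 and from 6.61 ± 1.73 to 2.57 ± 0.04. The ES cells had been grown on a fibroblast layer, whose part in these ES levels was not tested. The list median was 0, also with low values raised (adjusted p = 0.837). Among paralogs 10 to 13, 2 genes were tested and lower. Hoxc13 went from 6.14 ± 1.01 to 2.17 and Hoxd13 from 4.63 ± 0.98 to 2.17, the latter with no call once values under 4 were raised (log2 difference -0.63).

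Signalling lists differed in direction. In the retinoid list 12 of 15 genes were higher and 1 lower, with a median of 4.81 that did not change with low values raised (adjusted p = 0.000142), and adjusted p = 0.0779 with an estimated correlation. Cyp26b1, a retinoic acid hydroxylase gene, was at least 172-fold higher and Meis1 99.1-fold higher. In the hedgehog list 6 of 10 genes were higher and 1 lower, with a median of 3.36, or 2.47 with low values raised (adjusted p = 0.0171), and adjusted p = 0.182 with an estimated correlation. Nkx2-2 and Nkx2-9 were at least 316-fold and 121-fold higher. In the FGF and ERK list 12 of 20 genes were lower and 3 higher, with a median of -2.97 that did not change with low values raised (adjusted p = 0.0291), and adjusted p = 0.182 with an estimated correlation. Etv5, a transcription factor gene induced by FGF, was at least 565-fold lower. Without ES replicate 3 the hedgehog and FGF and ERK calls ended at adjusted p = 0.0544 and 0.0655.

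Of the remaining lists 2 were called, both lower. The fibroblast list had 11 of 12 genes lower and a median of -5.18, or -4.83 with low values raised (adjusted p = 0.00326), with adjusted p = 0.452 with an estimated correlation. The ES cells had been grown on a fibroblast layer. Col1a1 went from 11.09 ± 1.38 in ES cells to 2.17, at least 136-fold lower, or 78.7-fold without ES replicate 3. The intestinal epithelium list had 5 of 6 genes lower and a median of -8.12, or -6.46 with low values raised (adjusted p = 0.011), with adjusted p = 0.0847 with an estimated correlation and no call without the filter on low values (adjusted p = 0.215). Its falling members were epithelial genes that ES cells express as well, such as Cdh1, the E-cadherin gene, and Epcam, at least 548-fold and 445-fold lower. The ventral interneuron and floor plate list missed the test against other genes (adjusted p = 0.107) with 3 of 4 genes higher, 0 lower and a median of 5.64, or 4.55 with low values raised, and passed fry, a test of the list by itself that 22 of the 24 lists tested passed here (adjusted p = 5.38e-06). The tail bud list likewise missed the first test (adjusted p = 0.199) and passed fry (adjusted p = 0.00031), with 6 of 11 genes higher, 2 lower and a median of 1.08, or 0.64 with low values raised. Other lists without a call had medians of -2.96 (midbrain and hindbrain, 1 higher and 3 lower of 6, adjusted p = 0.312), -0.28 (motor columns, 3 and 3 of 10, 0.608), -1.62 (glia, 2 and 2 of 6, 0.837), -4.57 (neural crest, 1 and 3 of 4, 0.288), 0.76 (endoderm, 3 and 1 of 8, 0.58), -0.03 (mesoderm, 0 and 2 of 7, 0.58) and -4.71 (trophoblast, 0 and 5 of 6, 0.053). The trophoblast list passed under 5 processing alternatives, with adjusted p from 0.0293 to 0.0415, without ES replicate 2 (0.0099) and without motor neuron replicate 2 (0.0497). The Polycomb list had 5 genes higher and 10 lower of 26, with a median of -0.77 (adjusted p = 0.107). Its largest changes were in Phc2 (29.3-fold higher) and Cbx7 (28.5-fold lower), where the fall was in 1 of 3 probe sets, as the others went from 5.26 to 5.35 and from 5.99 to 6.42. The cell cycle list had 0 genes higher and 10 lower of 28, with a median of -0.68 (adjusted p = 0.107), and passed without ES replicate 2 (0.0465). The stress list had 2 higher and 10 lower of 17, with a median of -1.25 (adjusted p = 0.0815), and passed without the filter on low values (0.0405). The hypoxia and glycolysis list had a median of 0.19 and a mean of -0.54, and its test pointed down without a call (adjusted p = 0.878); 4 genes were higher and 5 lower, and 2 and 5 when adjusted over the list alone.

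Probe sets of the same gene often differed in this comparison. Among called genes with several probe sets, 110 of 1274 higher genes (8.63%) and 504 of 1536 lower genes (32.8%) had a probe set called the opposite way. Of the 2 tested Meis1 probe sets 1 was called higher, and the other went from 5.27 to 4.18. Median centring moved the median difference of all genes from -0.076 to 0.088. It also turned the balance of the calls, to 3118 genes higher and 3051 lower, as did the mean of all probe sets, with 2933 and 2518, and each probe set counted by itself, with 6873 and 6015.

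The second comparison asked what induced Cdx2 with FGF changed in day 5 cultures. If only these cultures received the lower doses of retinoic acid and hedgehog agonist, those doses are part of the difference. The 7 tested Hox genes of paralogs 7 to 9 rose, while 10 of 11 Hox genes of paralogs 1 to 5 and 31 of 32 pan-neuronal genes fell. Of the 7, Hoxa7, Hoxa9, Hoxb9 and Hoxc9 were tested only through the Cdx2 and FGF arrays, so they could only come out higher. With an estimated correlation the adjusted p was 0.102 for the list of paralogs 6 to 9, 0.05 for that of paralogs 1 to 5 and 0.0315 for the pan-neuronal list. Hoxc8 rose at least 202-fold, from 2.31 to 11.66 ± 0.13 (SD, n = 3; log2 difference 9.35, SE 0.36, adjusted p = 1.39e-07), while Hoxc5 fell 31.1-fold, from 11.46 ± 0.26 to 6.5 ± 0.79 (log2 difference -4.96, SE 0.37, adjusted p = 9.75e-06). Dcx fell 141-fold, from 12.83 ± 0.36 to 5.7 ± 1.1, or 214-fold without Cdx2 and FGF replicate 1. Of 7 tested mesoderm genes, out of 20 with a probe set, 5 rose (adjusted p = 0.0315 with an estimated correlation), as did the smooth muscle actin gene Acta2, at least 517-fold. In all, 1220 genes (11.2%) were higher and 939 (8.61%) lower in Cdx2 and FGF cultures, with all 3 arrays of the dimmer group under 4 for 246 and 198 of them.

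Among Hox paralogs 6 to 9, 7 of 9 tested genes were higher and 1 lower. Of these, Hoxa7, Hoxa9, Hoxb9 and Hoxc9 lay under 4 on all ES and motor neuron arrays. They were tested only through the Cdx2 and FGF arrays and could only come out higher, which raised the share and the median. The list call held without the filter on low values. Hoxb7, too dim to be tested, read 3.02 in motor neuron cultures and 4.04 in Cdx2 and FGF cultures. Hoxa9, Hoxb9, Hoxc9 and Hoxd9 were at least 143-fold, 106-fold, 71.9-fold and 57.7-fold higher, Hoxd8 42.4-fold and Hoxa7 at least 8.45-fold. The bound for Hoxd9, which read 11.01, 10 and 8.55, was 90.6-fold without Cdx2 and FGF replicate 3. Hoxb6 was lower, from 12.98 ± 0.25 to 10.19 ± 0.37 (log2 difference -2.79, adjusted p = 7.25e-05). The chosen probe set of Hoxc6 read 4.62 and 4.69 ± 0.11, whereas 2 other probe sets of the gene went from 2.17 to 5.66 and from 2.27 to 5.67, and the mean of all its probe sets was called at a log2 difference of 2.32. The list median was 7.28, or 5.85 with low values raised (adjusted p = 1.21e-05), with adjusted p = 0.102 with an estimated correlation.

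Among Hox paralogs 1 to 5, 10 of 11 genes were lower over all genes tested, and 11 when adjusted over the list alone. Hoxd3 fell 22-fold, Hoxb4 13.2-fold, Hoxa4 12.9-fold, Hoxa5 11.4-fold and Hoxb5 11.3-fold, the last from 14.14 ± 0.06 to 10.64 ± 0.15. Hoxa3, Hoxa2, Hoxb2 and Hoxc4 had log2 differences of -2.63, -2.38, -1.9 and -1.76. Hoxb3 had a difference of -1.92 with adjusted p = 0.0702, which passed with only the 6 arrays compared (0.000406), array weights (0.000184), the mean of its probe sets (0.00509) and low values raised (0.0154). The list median was -3.5 with or without low values raised (adjusted p = 1.37e-10); with an estimated correlation it was at adjusted p = 0.05, which misses the threshold. Of 10 genes of paralogs 10 to 13 2 were tested, Hoxc13 and Hoxd13, which read 2.17 in both groups. Among those too dim to be tested, Hoxc10 read 6.14, 4.88 and 2.55 against 2.21 ± 0.05, and Hoxa10 3.02 ± 0.74 against 2.17.

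**Figure D2:**
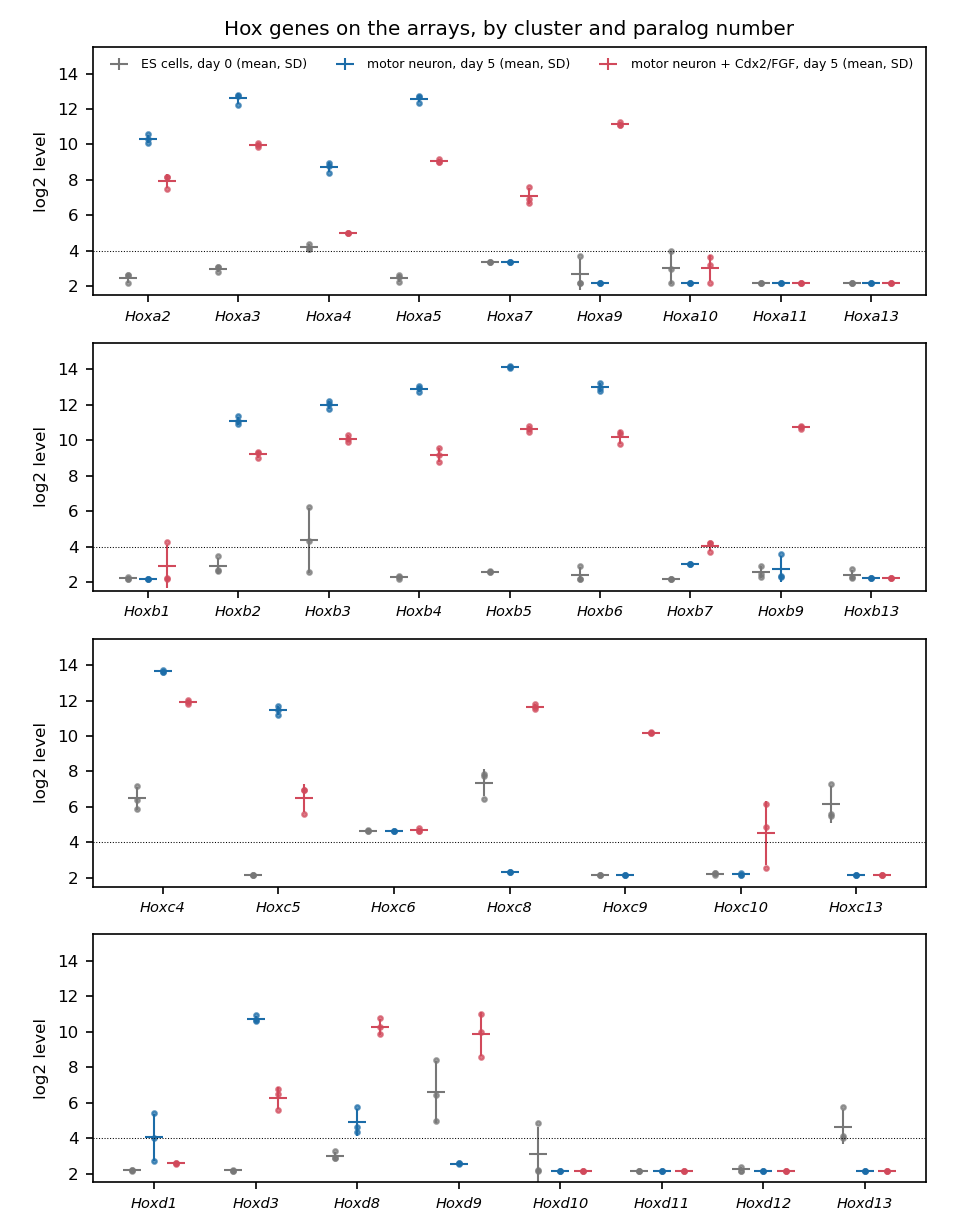
Levels of Hox genes by cluster and paralog number; the vertical axis is the log2 level, points are arrays, horizontal marks are means of 3 arrays, vertical bars are SDs and the dotted line is the level of 4. Hoxc9 lay at 2.17 in ES cells and motor neuron cultures and at 10.17 in Cdx2 and FGF cultures, while Hoxb5 went from 2.58 to 14.14 and to 10.64.

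Neuronal genes fell. Of 32 pan-neuronal genes 31 were lower over all genes tested, and 32 when adjusted over the list alone, with a median of -3.47, or -3.39 with low values raised (adjusted p = 4.8e-25; 0.0315 with an estimated correlation). Nhlh2 and Cntn2, an axonal adhesion gene, each fell 39-fold, and the growth cone gene Gap43 fell 22.5-fold. In the motor neuron and ventral progenitor list 13 of 18 genes were lower and 1 higher, or 14 and 1 when adjusted over the list alone, with a median of -3.1, or -2.73 with low values raised (adjusted p = 5.51e-09; 0.018 with an estimated correlation). Slc18a3 was at least 134-fold lower and Neurog1 fell 54-fold, and Prph, a peripheral neuron filament gene, was at least 26.9-fold lower (17.9-fold without motor neuron replicate 1 and 47.5-fold without replicate 3). Nkx6-1, chosen after its values were seen, had a difference of 0.01, at 12.06 ± 0.1 in Cdx2 and FGF cultures. In the neural progenitor list 7 of 21 genes were lower and 2 higher, with a median of -0.67 (adjusted p = 0.00141), and adjusted p = 0.0623 with an estimated correlation. Fabp7 fell 59.5-fold and Pou3f3 14.4-fold, whereas Zic2 was at least 30.1-fold higher. In the motor column list 6 of 10 genes were lower and 2 higher, or 7 and 2 when adjusted over the list alone, with a median of -1.69 (adjusted p = 0.0122), and adjusted p = 0.099 with an estimated correlation and 0.058 with only the 6 arrays compared. Lhx4 fell 14.2-fold and Lhx3 12-fold, while Etv4 and Aldh1a2, a retinaldehyde dehydrogenase gene, were at least 10.2-fold and 7.19-fold higher.

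Over all genes, the largest falls were in Sncg (at least 786-fold lower), Cyp26b1 (at least 172-fold lower), Dcx, Slc18a3, Runx1t1 (at least 96.7-fold lower) and Cdk5r2, a neuronal activator of Cdk5. The largest rises were in Acta2, the interferon-induced gene Ifitm1 (at least 412-fold), the smooth muscle gene Tagln (at least 330-fold), the cardiac actin gene Actc1 (at least 284-fold) and the keratin gene Krt19 (at least 220-fold). Acta2 went from 3.66 ± 1.27 to 13.37 ± 0.06 (log2 difference 9.72, SE 0.94, adjusted p = 5.13e-05) and Actc1 from 2.6 ± 0.16 to 12.15 ± 0.07 (log2 difference 9.55, SE 0.22, adjusted p = 1.47e-08).

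Targets of FGF and ERK signalling rose. In that list 11 of 20 genes were higher and 1 lower, or 12 and 1 when adjusted over the list alone, with a median of 1.9, or 1.89 with low values raised (adjusted p = 1.21e-05; 0.0449 with an estimated correlation). Etv5 was at least 88.4-fold higher, the ERK pathway inhibitor gene Spry1 55.5-fold, and the immediate early gene Egr1 at least 15.6-fold. In the tail bud list 5 of 11 genes were higher and 1 lower, with a median of 0.99 and no call (adjusted p = 0.115). Cdx2 was one of the 5. The retinoid list had 3 genes higher and 3 lower of 15, with a median of -0.35 (adjusted p = 0.174), with Cyp26b1 lower and Tgm2 11.3-fold higher. The hedgehog list had 4 higher and 1 lower of 10, with a median of 1.28 (adjusted p = 0.115). Hsd11b2 was 21.2-fold higher and Nkx2-2 18-fold lower.

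Mesoderm genes rose. In the mesoderm list 5 of 7 genes were higher, or 6 when adjusted over the list alone, and 0 lower, with a median of 6.55, or 4.74 with low values raised (adjusted p = 1.72e-06; 0.0315 with an estimated correlation). Meox1, a somite factor, was at least 123-fold higher, and the forkhead genes Foxc1, Foxf1 and Foxc2 at least 33.3-fold, 31.3-fold and 26.7-fold higher. Of 20 list members with a probe set, 7 were tested. Meox1, Foxc1, Foxf1 and Tbx1 lay under 4 on all ES and motor neuron arrays, and so were tested only through the Cdx2 and FGF arrays. These genes could only come out higher, which raised the share and the median, while the list call held without the filter on low values. In the fibroblast list 11 of 12 genes were higher, with a median of 4.21, or 3.42 with low values raised (adjusted p = 6.03e-06), and adjusted p = 0.268 with an estimated correlation. Ccn1 rose 77.9-fold and the fibronectin gene Fn1 18.8-fold, whereas Thy1, chosen after its values were seen, read 2.17 in both groups. The neural crest list had 3 higher and 1 lower of 4, with a median of 4.14 (adjusted p = 0.0554), and passed under quantile normalization (0.0413) and median centring (0.0392). It also passed without Cdx2 and FGF replicate 2 (0.0445) or 3 (0.0473) and without motor neuron replicate 1 (0.041). Ets1 was at least 44.5-fold higher, Snai2 at least 13.8-fold and Twist1 15.3-fold, and Ngfr 6.79-fold lower. These 3 higher genes are also expressed in mesenchyme.

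Lists of further cell types did not pass the test. The endoderm list had a median of 1.15 (adjusted p = 0.126), with 4 genes higher and 1 lower of 8, or 5 and 1 when adjusted over the list alone, and passed with a filter at 6 (0.0408) and the mean of probe sets (0.0179); the endocytic adaptor gene Dab2 rose 46.9-fold. The trophoblast list had a median of 2.38 (adjusted p = 0.105), with 3 of 6 genes higher, or 4 when adjusted over the list alone; Krt18 rose 7.53-fold. The intestinal epithelium list, for another tissue in which Cdx2 acts, had a median of 0 (adjusted p = 0.672), with Epcam at least 4.28-fold higher, or 6.59-fold without Cdx2 and FGF replicate 3, as the 1 call of 6. Medians were 1.77 for ventral interneurons and floor plate (adjusted p = 0.0554), 0 for midbrain and hindbrain (0.431), -0.32 for glia (0.681) and 0 for pluripotency (0.979). The ventral interneuron and floor plate list passed with low values raised (adjusted p = 0.0405), the mean of probe sets (0.0407), quantile normalization (0.0413) and median centring (0.0392). It also passed without Cdx2 and FGF replicate 1 (0.0454) and without motor neuron replicate 1 (0.044) or 2 (0.037). In it the floor plate factor gene Foxa2 rose 3.89-fold. In the pluripotency list Sall4 rose 5.17-fold and Nr0b1 was at least 3.52-fold lower.

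The cell cycle list shifted up, with 5 of 28 genes higher, 0 lower and a median of 0.57 (adjusted p = 0.000358), and adjusted p = 0.395 with an estimated correlation. The mitotic checkpoint gene Bub1b rose 2.9-fold; with the mean of its probe sets the log2 difference was 0.98, under the minimum of 1. The hypoxia and glycolysis list had 5 of 17 genes higher, 0 lower and a median of 0.43 (adjusted p = 0.00531), and adjusted p = 0.425 with an estimated correlation. Pfkp rose 16.3-fold and Slc2a3, a glucose transporter gene, 3.17-fold. The stress list had 5 of 17 genes higher and a median of 0.3 (adjusted p = 0.0833), and passed without Cdx2 and FGF replicate 3 (0.0408), without the filter on low values (0.0228) and with the mean of probe sets (0.0452). The higher genes included the heat shock gene Hspa1b, at least 21.6-fold higher, or 32.7-fold and 12.8-fold without Cdx2 and FGF replicates 1 and 3, its arrays reading 7.23, 8.13 and 9.93.

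The Polycomb list did not pass the test. It had 0 of 26 genes higher, 1 lower and a median of -0.04 (adjusted p = 0.555). The H3K27 methyltransferase gene Ezh2 had a difference of -0.1 (SE 0.12), Suz12 -0.08 (SE 0.09) and Eed 0.45 (SE 0.15, adjusted p = 0.0517). The demethylase genes Kdm6b and Kdm6a differed by -0.07 and 0.18. Of 3 tested Kdm6b probe sets 1 was called higher (5.14 to 6.43), as were 1 of 5 for Mtf2 (4.37 to 7.26) and 1 of 4 for Rbbp4 (4.81 to 5.86), while 1 of 2 for Cbx8 was called lower. The lower gene, Jarid2, differed by -1.08 (SE 0.16, adjusted p = 0.000789), and fell short of the minimum difference without Cdx2 and FGF replicate 2 (-0.96), with the mean of its probe sets (-0.97) and without s_at and x_at probe sets (-0.84). Ezh1 had a difference of 1.52 with adjusted p = 0.0707, and passed with only the 6 arrays compared (0.0183) and with array weights (0.00478). Pcgf5, at 0.54, passed with the mean of its probe sets (log2 difference 1.17, adjusted p = 0.0226). Of 2 tested probe sets each, 1 was called higher for Ezh1 and Pcgf5.

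Probe sets of a gene rarely disagreed here: 3 of 519 higher genes (0.578%) and 0 of 396 lower genes with several probe sets had one called the opposite way. Of 2 tested probe sets each, 1 was called for Epcam, Etv4 and Fn1, and 3 of 5 were called for Runx1t1.

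**Figure D3:**
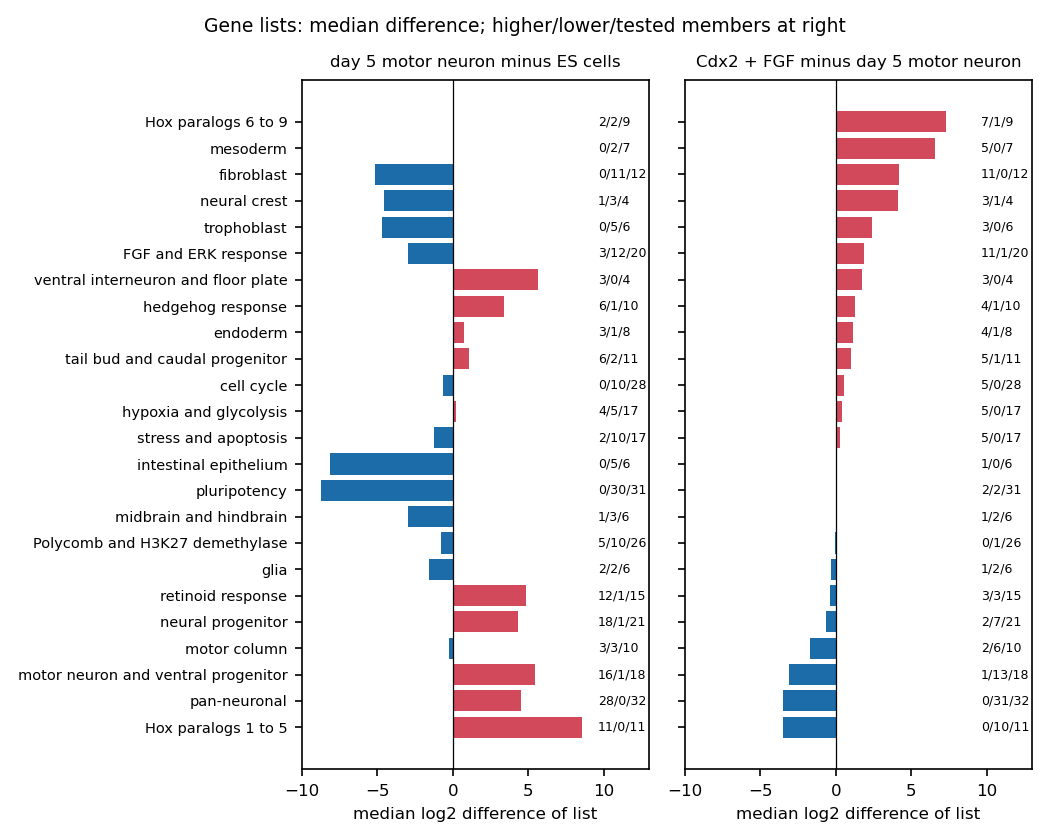
Median log2 difference of each gene list, as bars on the horizontal axis, for motor neuron cultures against ES cells on the left and for Cdx2 and FGF cultures against motor neuron cultures on the right; the numbers at the right give genes called higher, called lower and tested. The median of Hox paralogs 6 to 9 was 0 on the left and 7.28 on the right, and that of the pan-neuronal list 4.48 and -3.47.

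The third comparison set the Cdx2 and FGF cultures against the ES cells, with the contrast in amplification controls described for the first comparison. Of 31 pluripotency genes 30 were lower, and 17 of 21 neural progenitor genes were higher and 1 lower, each with adjusted p = 0.0468 with an estimated correlation. Hox genes were higher for 10 of 11 of paralogs 1 to 5 and 8 of 9 of paralogs 6 to 9, and both list calls were lost with an estimated correlation (adjusted p = 0.136 and 0.151). Most of these Hox genes lay under 4 on all ES arrays, so they had little room to come out lower. Hoxb5os rose at least 1430-fold, from 2.21 ± 0.08 to 14.48 ± 0.07 (SD, n = 3; log2 difference 12.27, SE 0.17, adjusted p = 3.52e-10), and Dppa2 was at least 1040-fold lower. Of the genes tested 2774 (25.4%) were higher and 2971 (27.2%) lower, with all 3 arrays of the dimmer group under 4 for 417 and 623 of them.

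Next to Hoxb5os, H1f4 and the microtubule-associated ligase gene Mid1 (at least 693-fold) had the largest rises, and Dppa2, Fgf4 and AU018091 the largest falls. The pluripotency list had a median of -8.72, or -7.3 with low values raised (adjusted p = 5.26e-15). The median of Hox paralogs 1 to 5 was 5.73, or 5.19 with low values raised (adjusted p = 5.14e-06; 0.136 with an estimated correlation), and that of paralogs 6 to 9 was 7.3, or 6.17 with low values raised (adjusted p = 0.000213; 0.151 with an estimated correlation). Hoxa9 was at least 143-fold higher, Hoxc8, which read 7.37 on the ES arrays, 19.5-fold, and Hoxd9 9.47-fold. Without 1 array the fold of Hoxd9 was 5.37 (ES replicate 1), 17.8 (ES replicate 2) or 14.9 (Cdx2 and FGF replicate 3).

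The neural progenitor list had a median of 3.29, or 3.02 with low values raised (adjusted p = 1.95e-05; 0.0468 with an estimated correlation). Pou3f2 was at least 149-fold higher. The motor neuron list had 11 genes higher and 3 lower of 18, with a median of 2.36, or 1.31 with low values raised (adjusted p = 0.0156), and adjusted p = 0.136 with an estimated correlation. Nkx6-1 was at least 266-fold higher and Isl1 31-fold. The pan-neuronal list had 18 higher and 7 lower of 32, with a median of 1.33 (adjusted p = 0.0425), and adjusted p = 0.51 with an estimated correlation. This call also ended without ES replicate 1 (0.056), without ES replicate 2 (0.0647), and under 5 further alternatives (median centring, a filter at 6, low values raised, array weights and a replicate block), at adjusted p from 0.0522 to 0.0676. Neurod4 was at least 195-fold higher and Ebf1 21.2-fold lower.

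Other lists that passed all lost their call with an estimated correlation. The retinoid median was 4.21, or 3.65 with low values raised, with 12 of 15 genes higher (adjusted p = 0.000126), and adjusted p = 0.0921 with an estimated correlation. The hedgehog median was 6.06, or 4.63 with low values raised, with 7 of 10 genes higher and 1 lower (adjusted p = 0.00447), and adjusted p = 0.151 with an estimated correlation. The tail bud median was 4.26, or 2.98 with low values raised, with 7 of 11 genes higher and 1 lower (adjusted p = 0.0293), and adjusted p = 0.396 with an estimated correlation. The ventral interneuron and floor plate list had 4 of 4 genes higher and a median of 6.7, or 5.61 with low values raised (adjusted p = 0.0198). The mesoderm list had 5 of 7 higher and 1 lower and a median of 6.12, or 4.3 with low values raised (adjusted p = 0.0198). Both stood at adjusted p = 0.151 with an estimated correlation. Without the filter on low values, the tail bud, ventral interneuron, mesoderm and intestinal epithelium calls ended (adjusted p = 0.058, 0.263, 0.222 and 0.165), and with a filter at 6 the tail bud call (0.0634). Foxa2 was at least 158-fold higher, Greb1 at least 81.3-fold, Meox1 at least 123-fold and Tbx1 at least 19.7-fold. The intestinal epithelium median was -7.37, or -6.45 with low values raised, with 5 of 6 genes lower (adjusted p = 0.00447), and adjusted p = 0.099 with an estimated correlation. The fibroblast list, with 2 genes higher and 4 lower of 12, or 1 and 3 when adjusted over the list alone, had a median of -0.21 and no call (adjusted p = 0.739). The cell cycle list had a median of -0.11 (adjusted p = 0.981). The other 10 lists tested had no call; with a filter at 6 the midbrain and hindbrain (0.0164) and Polycomb (0.0499) lists passed, the former also with the mean of probe sets (0.0401).

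Among called genes with several probe sets, 115 of 1211 higher genes (9.5%) and 511 of 1342 lower genes (38.1%) had a probe set called the opposite way. Under quantile normalization and median centring the median difference of all genes ran from -0.087 to 0.099, against -0.004 in the deposited values. The balance of the calls turned under median centring, with 2970 genes higher and 2779 lower, with the mean of all probe sets (2929 and 2102), without s_at and x_at probe sets (2872 and 2835) and with each probe set counted by itself (6758 and 5312). Of 4 tested Ebf1 probe sets 2 were called lower.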

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

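The tests of degraded RNA and of cells in S phase were chosen after the results were seen, and those of priming and of 3′ bias before. The first 3 results below come from control probe sets, which enter no gene call or list test and which the report compares only as a check of the arrays. The 3′ control probe set for 18S ribosomal RNA was 9.13 higher in day 5 motor neuron cultures than in ES cells. The 3′ minus 5′ difference of the Actb controls was lower there by a difference of -2.11, and that of the Tfrc controls by a difference of -7.75. Among 1979 tested probe sets without exactly 1 gene name, which were left out of the gene counts, 188 were called higher and 136 lower in Cdx2 and FGF cultures than in motor neuron cultures.

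The ES arrays differed from both kinds of day 5 array in control and histone probe sets and in how well probe sets of a gene agreed. Degraded RNA with the same priming was predicted to leave 18S ribosomal RNA, which has no poly(A) tail, labelled alike. The lowest day 5 array instead exceeded the highest ES array by at least 3.27 on each 18S control probe set. That gap is part of the pattern and was seen before the test was chosen. The test therefore cannot decide, and degraded RNA stays open. More cells in S phase at day 5, another source of histone mRNA, is argued against for the histone rises by the 28 cell cycle genes. Their differences ran from -2.22 to 0.85 with a median of -0.68, 0 higher and 10 lower. The camera adjusted p was 0.107, or 0.67 with an estimated correlation, and the fry adjusted p was 0.00606. A different priming or amplification of the RNA may account for the pattern, since replication-dependent histone genes, whose mRNAs lack a poly(A) tail, had a median difference of 3.06. Histone genes are themselves part of the pattern, however, and their median level per array overlapped between ES and motor neuron arrays. A different 3′ bias may be part of the cause, since the range of a gene's probe sets, over the spread of all differences, was 2.44 times larger against ES cells than between the day 5 groups.

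Arrays of 3 against 3 allow 10 splits, too few for a share under 0.05. In each comparison 1 split, the real one, called as many genes, and the highest of the other splits called 0. The real counts were 6172 for motor neuron cultures against ES cells, 2159 for Cdx2 and FGF cultures against motor neuron cultures, and 5745 for Cdx2 and FGF cultures against ES cells.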

How the results depend on the processing

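The alternatives without ES arrays 2 and 3 and those on agreement between probe sets were chosen after the results were seen; the others were planned. Leaving out single arrays gave 2701 to 2860 genes higher and 3192 to 3365 lower for motor neuron cultures against ES cells, 991 to 1212 and 806 to 912 for Cdx2 and FGF cultures against motor neuron cultures, and 2629 to 2806 and 2850 to 3011 for Cdx2 and FGF cultures against ES cells. In the second of these, the medians ran from -3.56 to -3.42 for Hox paralogs 1 to 5 and from 6.7 to 7.93 for paralogs 6 to 9. Counts moved by over 1.5 times with each probe set counted by itself, which counts more features: 6873 and 6015, 2343 and 1845, and 6758 and 5312. With no minimum fold change, Cdx2 and FGF against motor neuron cultures gave 2016 and 1473, since smaller differences then count. With an estimated correlation, Hox paralogs 1 to 5 at -3.5 (adjusted p = 0.05) and 6 to 9 at 7.28 (adjusted p = 0.102) were no longer called, since that test widens with the correlation of the members. Hoxd8 in motor neuron cultures against ES cells reversed to -0.08 with the mean of its probe sets, which go opposite ways. A replicate block gave 2826 and 3345, 1206 and 931, and 2784 and 2973, with adjusted p = 5.47e-10 and 3.09e-05 for the Hox lists. Deviations of same-numbered arrays had correlations of -0.03 to 0.08 over genes. In the second comparison these were 0.04 to 0.08, against -0.1 to 0.05 for different numbers. Such small correlations give little sign of pairing but cannot exclude it, and the labels do not state it. Without ES arrays 2 and 3, where the remaining ES array is assumed to vary like the other groups, the counts were 2831 and 3325 for motor neuron cultures and 2803 and 2954 for Cdx2 and FGF cultures. Leaving out genes with an opposite probe set gave 2716 and 2842, 1217 and 939, and 2659 and 2460, and requiring all probe sets to be called alike 2388 and 2362, 1019 and 821, and 2260 and 2024. Of 72 list results, 24 lost their call with an estimated correlation and 29 gained one with fry. Of the named gene results with the mean of all probe sets, 319 held, 14 lost and 6 gained their call and 1 reversed. In the second comparison the calls of Aldoc and Tshz1 ended without each of the 6 arrays in turn. Signal near the floor of 2.165 limits what the arrays resolve, so folds against a group with arrays under 4 are lower bounds.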

Other observations

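The tests of feeder fibroblasts, of a lower share of neurons, of Y-linked RNA and of a general loss of signal were chosen after the results were seen, as were the 37 gene families, sorted by symbol, and the genes named here. In Cdx2 and FGF cultures against motor neuron cultures, several families were higher: 8 of 15 collagens (1 lower; median log2 difference 2.86, camera adjusted p = 0.00513), 7 of 12 integrins (1 lower; 1.44, 0.00513), 3 of 6 laminins (1.49, 0.0469), 4 of 10 myosins (0.77, 0.0199), 2 of 4 tropomyosins (1.58, 0.0499) and 6 of 8 annexins (4.35, 0.000203). Myl9, a smooth muscle myosin light chain gene, went from 5.24 to 13.27 (log2 difference 8.03, SE 1.11, adjusted p = 0.000501, n = 3), Itga8 from 2.17 to 8.07 and Anxa2 from 5.12 to 11.18. With an estimated correlation none of the 37 families was called: the adjusted p was 0.389, 0.197, 0.405, 0.156, 0.405 and 0.114 for these 6.

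Other families were lower in the same cultures, while potassium channels (3 higher and 4 lower of 13; median 0.04, adjusted p = 0.877), sodium channels (adjusted p = 0.0812) and glutamate receptors (adjusted p = 0.264) had no call. Of 11 protocadherins 9 were lower and 1 higher (median -2.91, adjusted p = 6.82e-06; adjusted p = 0.0575 with an estimated correlation), with Pcdhb19 going from 8.44 to 3.61. Of 10 calcium channel genes 6 were lower (-1.55, 0.000331), as were 6 of 9 synaptotagmins (-2.03, 0.000627), 4 of 4 LIM homeobox genes (-3.71, 0.000211) and 4 of 7 POU genes (-2.49, 0.000311), each with adjusted p = 0.114 with an estimated correlation. Cacng4 went from 9 to 2.24 (log2 difference -6.76, SE 0.23, adjusted p = 7.98e-08), where the lower level lay near the floor, so the size of the difference depends on the floor. Of 4 genes with interferon-induced names 4 were higher (2.29, adjusted p = 0.000331; 0.114 with an estimated correlation), with Ifit2 going from 5.1 to 7.91.

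Mesoderm and smooth muscle genes were higher in Cdx2 and FGF cultures. Feeder fibroblasts carried over are argued against for 4 of the 5 higher mesoderm genes, as far as the ES arrays, from cells on feeders, can be compared: with low values raised, the lowest Cdx2 and FGF array exceeded the highest ES array by a median of 4.52 over the 5, while Foxc2, at -0.15, stays open. Feeder fibroblasts as the source of Acta2 and Tagln stay open. Other fibroblast genes over 7 on ES arrays 1, 2 and 3 fell short of the change in these 2 genes by medians of -4.27, -5.51 and -4.4. This held for 5 of 5, 11 of 12 and 10 of 12 genes. Col1a1 read 12.68 on ES array 3 and 7.09 to 7.11 in Cdx2 and FGF cultures, beside similar Acta2 levels. The shortfall cannot decide, since Acta2 and Tagln were chosen for their large rises. The ES and day 5 arrays also differed in amplification controls. The test of a lower share of neurons alone cannot decide either. List medians were 6.55 for mesoderm (4.74 with low values raised), 1.15 for endoderm, 0 for intestinal epithelium and -0.67 for neural progenitors. These markers did not rise alike, and the mesoderm median exceeded the neural progenitor median by 7.22. However, 4 of the 5 higher mesoderm genes were tested only because they were high in these cultures, so a large gap was likely in advance. Mesoderm-like cells in these cultures are a candidate explanation. The mesoderm list was called at an adjusted p of 0.0315 with an estimated correlation. That call restates the rise to be explained, so it cannot favour one source over another. The parts played by Cdx2, FGF and the lower doses of retinoic acid and hedgehog agonist in the growth protocol stay open. Cdx2 and FGF were given together, and the protocol does not say which cultures received the lower doses.

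The Y-linked genes Uty and Eif2s3y were lower in day 5 motor neuron cultures than in ES cells, by log2 differences of -4.84 and -6.11, while 5.17% and 3.06% of tested genes fell as much, and Xist differed by -6.26. Uty and Xist read 2.17, the floor, on every day 5 array. The sizes of their differences, and the share given for Uty, therefore depend on the floor. A general loss of signal as the whole cause is argued against by 6 probe sets of the X-linked homologs Eif2s3x and Kdm6a, with a median of -0.19 (SE 0.64 across probe sets), although 2 of the 3 for Kdm6a had differences of -2.77 and -2.15. Y-linked RNA of feeder fibroblasts in the ES arrays was predicted to be lowest in ES replicate 1, where S100a4, Lox and Mgp lay near the floor. Uty and Eif2s3y were instead on average 1.04 higher there, the opposite of the prediction. Other fibroblast genes, such as Col1a1 at 10.15 and Timp1 at 8.79, were not near the floor on that array. As 1 array cannot exclude it, a feeder contribution stays open. A difference between the cells behind the arrays, such as loss of the Y chromosome or another line than the 1 named for all 9 arrays, was not tested and stays open.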
